A study of Homo sapiens with 4 samples.

How the data were processed

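The series measured messenger RNA by sequencing in THP-1 cells, a human monocytic leukaemia line, in 4 libraries. Per the labels' protocols, the cells were turned into macrophages with the phorbol ester PMA at 100 ng/ml for 24 h. The 2 control libraries came from these macrophages alone. The other libraries came from macrophages kept for 48 h below a membrane with 0.4 µm pores that carried HepG2 or MHCC-97H cells, both human hepatoma lines, with 1 library per line. The controls were taken from the sample titles and the co-cultures from the treatment labels. A culture time is recorded for the co-cultures only, so how long the controls were kept after PMA is not known here. Nothing in the labels says whether the 2 controls came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

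Per the labels' protocols, RNA was prepared with TRIzol, libraries with an Illumina TruSeq kit, and reads were filtered with SeqPrep and Sickle. Reads were mapped with TopHat and quantified with Cufflinks, per the submitters' processing notes. The tool versions, the gene annotation and the strandedness are not given in the sources used here. The authors deposited FPKM (fragments scaled to the length of the transcript and to the mapped fragments of the library) for 20311 genes in each library. Read counts were not used here, so the depth of each library is unknown and no counting interval is given. For any 2 libraries, the ratios of genes between 0.001 and 0.15 FPKM were searched for a common window of 0.05 on the log2 scale. The fullest window held 13.2% of the ratios for control 1 with HepG2 and 7.3% for control 2 with MHCC-97H. It held 3.4% to 4.8% for the other combinations, so whole reads were not recovered. The cause of this difference was not tested. The authors also deposited 2 tables of comparisons of 1 control with 1 co-culture library, listing FPKM, p-value and q-value for selected genes. These are called the authors' deposited table for each line. The log2 columns of these tables were not used, and ratios were recomputed from their FPKM columns.

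The build is GRCh38 per the submitters' processing notes. The positions printed in the deposited tables were checked against GENCODE release 44 on GRCh38 by gene identifier, and 3 of 113 and 3 of 124 genes lay within 1000 bp, with median offsets of 466716 and 427326 bp. Nearly all positions in those tables thus do not match GRCh38, and the build behind the values is uncertain. No position from those tables is printed, and every coordinate given below is the GRCh38 position in GENCODE release 44 of the identifier in the files. Current symbols were matched by Ensembl identifier for 19438 of the 20311 genes, and the other 873 kept the symbol in the files. All 13 mitochondrially encoded genes were listed at 0 in the 4 libraries, so no mitochondrial share was computed.

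Values were analysed as log2(FPKM + 1), without rescaling. A fold change on this scale understates the change of low genes. Genes with a mean over the 4 libraries of at least 1 FPKM were tested (10735 genes). The mean over all libraries was used so that abundant genes that fell were kept. Low genes that moved were still left out, and the list counts below cover tested members only. STAB1, a list member left out, was at 1.26 and 1.14 FPKM in the controls and 0.0872 and 0.0395 FPKM in the co-cultures. CD86, another, was at 0.162 and 0.0632 FPKM in the controls and 0.865 and 0.513 FPKM in the co-cultures. The test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, and the Benjamini-Hochberg adjusted p-value threshold was 0.05. All limma tests were two-sided.

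A fit of 2 groups compared both co-cultures (n = 2) with both controls (n = 2). There the tumour lines stand in as replicates, so that differences between them count as spread. A fit of 3 groups compared each co-culture (n = 1) with the controls and the co-cultures with each other. Its single residual degree of freedom lies between the controls, and limma set nearly the same spread for genes of the same level (median of 4774.4 total degrees of freedom, against 6.1 in the fit of 2 groups). In that fit each co-culture library is assumed to vary like the controls, and individual p-values from it are not printed for the changes in 1 co-culture.

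A count by size, with no test, took genes at least 2-fold higher or lower than each of the 2 controls on log2(FPKM + 1). The controls were set against each other as 1 library against 1, which compares with the counts of a co-culture against a single control and not with this stricter count.

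The named genes were fixed by rule before the data were examined. They are S100A9, S100A8, IL10 and MRC1, and per co-culture the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the size limit and beyond the difference between the controls. Up to 2 risers and 2 fallers per gene list past the size limit were added. The highest members of the hepatocyte and epithelial lists were added too. Other genes are given as examples of lists, or are said to be chosen after their values were seen. Values of some genes are not reported here.

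The gene lists were fixed before the data were examined, too. They cover tumour-associated and alternatively activated macrophage markers, classical activation, S100 genes, chemokines, interferon-stimulated genes, MHC class II, macrophage identity, complement, matrix remodelling, hypoxia and glycolysis, cholesterol synthesis, lipid handling, endoplasmic reticulum stress, heat shock, metallothioneins, NRF2 and iron, cell cycle, lysosome, hepatocyte, epithelial, mitochondrially encoded and ribosomal protein genes. A list's median log2 difference was ranked among 10000 random lists of the same size matched on expression in 20 bins. The percentile describes these libraries and is no test. Members called by the fit of 2 groups and by the fit of 3 groups were counted over all genes and adjusted over the list alone. The original plan named the fit of 3 groups for these counts, and the fit of 2 groups was added because its spread includes that between the co-cultures.

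Comparisons against the same controls share their chance values. The overlap of the co-cultures was therefore set beside the overlap of independent lists and beside 100 simulations of unchanged groups with shared simulated controls. In these all 4 libraries were drawn anew, with the same spread for genes of the same level and no library pairs. Genes that vary more than others of their level are not represented, so the simulations can understate the overlap expected by chance. The fits were tested on simulated data in which 200 genes were changed by a known fold. The changed genes were drawn only from the more abundant genes, and no library pairs were simulated. Recovery among the lower tested genes is therefore not known. All genes of a level had the same simulated spread, which is close to what the fit of 3 groups assumes. The few false calls below thus do not show how the fits behave where genes of a level differ in spread. For both co-cultures against both controls, limma recovered 98.5% of 2-fold and 100% of 4-fold changes, with 7 and 9 false calls among 10627 and 10610 genes. For HepG2 co-culture alone, it recovered 84% of 2-fold and 100% of 4-fold changes, with 13 and 9 false calls among 10614 and 10623 genes.

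The alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, TMM scaling factors computed over FPKM, quantile normalization, limma without the trend, a fold limit of 3, and leaving out each library in turn. A fit with the library pair as a block was added after seeing the data. It has a single residual degree of freedom for each gene, the difference between the changes in the 2 pairs. The rest of its 7.2 total degrees of freedom came from the spread shared over genes. Further software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.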

Results

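Messenger RNA was measured in 4 libraries of THP-1 macrophages: 2 of macrophages alone, 1 after 48 h of co-culture with HepG2 cells and 1 after 48 h with MHCC-97H cells. A porous membrane kept the hepatoma cells apart from the macrophages, so that secreted factors but not cells could pass. Values were deposited as FPKM, and the read depth behind them is unknown. Control 1, control 2, the HepG2 and the MHCC-97H library held 10709, 10504, 10705 and 10549 genes at 1 FPKM or more. The 10 most abundant genes made up 15.5% and 15.3% of the FPKM total in the controls, against 19.9% in the HepG2 and 19.2% in the MHCC-97H library. FTL, which encodes ferritin light chain, was the most abundant gene in both controls. CXCL8, a neutrophil chemokine gene, was the most abundant in the HepG2 library, and IL1B, the interleukin-1 beta gene, in the MHCC-97H library. Across the 10735 tested genes, the controls correlated with Pearson's r = 0.980 and the co-cultures with r = 0.986. Correlations between a control and a co-culture lay between 0.915 and 0.931. These correlations are across genes, which are not independent replicates.

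The first comparison asked which genes changed in macrophages co-cultured with either hepatoma line, and among them S100A9, which the study is named for. S100A9, a subunit of the secreted inflammatory protein calprotectin, rose from 4.84 ± 2.08 FPKM (SD, n = 2) in the controls to 397 FPKM with HepG2 and 369 FPKM with MHCC-97H. The difference on log2(FPKM + 1) was 6.09 ± 0.25 (SE; limma adjusted p = 1.37e-04). S100A8, which encodes the other calprotectin subunit, rose from 1.85 ± 0.41 FPKM (SD, n = 2) to 126 and 125 FPKM, by 5.48 ± 0.16 (SE; limma adjusted p = 8.25e-05). IL10, an immunosuppressive cytokine gene that the study used as a marker of tumour-associated macrophages, rose from 0.417 ± 0.134 FPKM (SD, n = 2) to 15.5 and 14.9 FPKM, by 3.52 ± 0.17 (SE; limma adjusted p = 1.82e-04). MRC1, the gene of the mannose receptor CD206 and the other marker, was listed at 0.0076 FPKM in control 1 and at 0 in the other libraries. A duplicate entry named MRC1L1 was listed at 0.0076 and 0.0273 FPKM in the controls and at 0 in both co-cultures. Both entries carry retired Ensembl identifiers, and the current MRC1 identifier is not among the genes listed, so these values do not give the level of the current gene model. On GRCh38, S100A9 lies on chromosome 1 from 153357854 to 153361023, S100A8 on chromosome 1 from 153390032 to 153391073, and IL10 on chromosome 1 from 206767602 to 206774541.

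Of the 10735 genes tested with limma on both co-cultures against both controls, 2085 (19.4%) passed the threshold, 914 higher and 1171 lower in co-culture. This count and those of list members below come from the fit without library pairs. A limma fit with control 1 paired with HepG2 and control 2 with MHCC-97H as a block, added after seeing the data, called 4993 genes, 2258 of them higher, so a gene that did not pass may still differ. The paired fit has a single residual degree of freedom for each gene and leans on the spread shared over genes. Its list counts are given below for some lists only, without a rule set in advance, and other lists changed too. In the paired fit 11 of 15 chemokine genes rose and 2 fell, and 17 of 22 hypoxia and glycolysis genes rose and 1 fell. Of 15 lipid handling genes 3 rose and 9 fell, and of 20 matrix genes 3 rose and 11 fell. The 4 libraries can be split into 2 and 2 in only 3 ways, so a count of splits cannot reach a share below 0.05. The largest rises included cytokine and chemokine genes. IL6, an inflammatory cytokine gene on chromosome 7 (22725884 to 22732002), went from 1.38 ± 0.27 FPKM (SD, n = 2) to 346 and 377 FPKM, a rise of 7.25 ± 0.15 on the log2 scale (SE; limma adjusted p = 4.33e-05). IL23A, the interleukin-23 subunit gene, rose by 7.01 ± 0.21 (SE), CCL1, a chemokine gene, by 7.13 ± 0.32 and IL36G, an interleukin-1 family gene, by 6.41 ± 0.27. The monocyte chemokine gene CCL2 rose by 5.54 ± 0.19 (SE), the prostaglandin synthase gene PTGS2 by 5.14 ± 0.17 and the growth factor gene CSF2 by 4.97 ± 0.17. SERPINB7, a serpin family gene, and MT2A, a metallothionein gene, rose by 5.85 ± 0.20 and 4.93 ± 0.21 (SE). The limma adjusted p-values of these 8 genes lay between 8.25e-05 and 1.58e-04.

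The largest falls included genes of lipid uptake and transport. FABP4, a fatty acid binding protein gene on chromosome 8 (81478419 to 81483236), went from 535 ± 57.3 FPKM (SD, n = 2) to 8.39 FPKM with HepG2 and 10.6 FPKM with MHCC-97H, and fell by 5.68 ± 0.17 on the log2 scale (SE; limma adjusted p = 8.25e-05). The scavenger receptor gene MSR1 fell by 5.37 ± 0.20 (SE) and CD36, another one, fell by 4.45 ± 0.22. MSR1 stood at 109 ± 14.8 FPKM (SD, n = 2) in the controls and at 2.04 and 1.31 FPKM in the co-cultures. APOC1, an apolipoprotein gene, fell by 3.81 ± 0.19 (SE). The transporter gene SLCO2B1 fell by 4.33 ± 0.20 (SE), the amino acid transporter gene SLC7A8 fell by 3.66 ± 0.19, and the cold-sensing channel gene TRPM8 fell by 3.61 ± 0.19. HSPB7, a small heat shock protein gene, fell by 4.50 ± 0.16 (SE), and PNOC, the nociceptin precursor gene, fell by 4.43 ± 0.17. CLMP, a cell adhesion gene, fell from 28.7 ± 4.16 FPKM (SD, n = 2) to 0.773 and 0.911 FPKM. TM4SF19 fell by 3.81 ± 0.14 (SE) from 688 ± 1.09 FPKM (SD, n = 2). The readthrough gene TM4SF19-DYNLT2B, which overlaps TM4SF19 and shares reads with it, had a difference of -3.92 ± 0.21 (SE), so the split between them is uncertain.

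**Figure D1:**
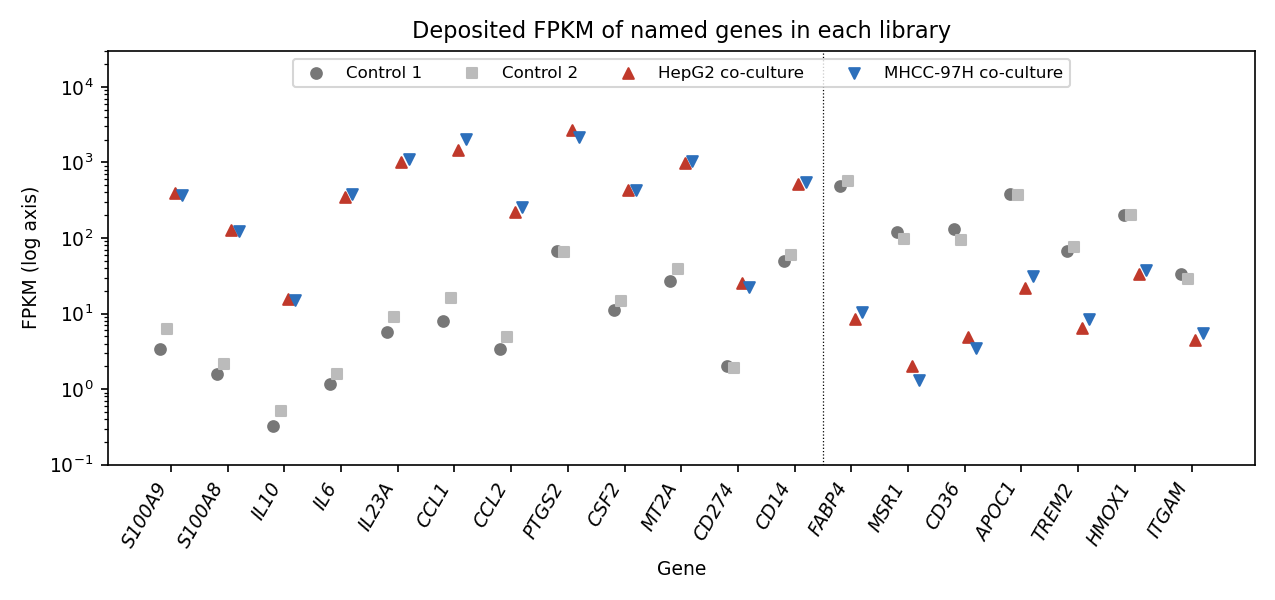
FPKM on a log axis of 19 named genes, with 1 point for each of the 2 controls and each co-culture library and no error bars. In the 12 genes left of the dotted line both co-cultures lie above both controls, and in the 7 to its right both lie below.

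Of 15 tested genes of classical macrophage activation, 11 rose, 1 fell and 3 did not pass, and adjusted over the list alone 12 rose and 1 fell. TNF, a central inflammatory cytokine gene, rose by 2.16 ± 0.15 (SE), IL1A by 3.32 ± 0.19 and IDO1, a tryptophan-degrading enzyme gene, by 3.11 ± 0.24, and the member that fell was the chemokine gene CCL5 (-0.89 ± 0.19). IL1B, at 12100 ± 2203 FPKM (SD, n = 2) in the controls and 21890 and 26590 FPKM in the co-cultures, did not pass (limma adjusted p = 0.083). Within the library pairs IL1B was 2.08-fold higher with HepG2 than in control 1 and 1.95-fold higher with MHCC-97H than in control 2, and it passed with the pair as a block (limma adjusted p = 1.36e-04). Of 15 chemokine genes, 11 rose and 4 did not pass, and adjusted over the list alone 11 rose and 2 fell. CXCL1 rose by 3.58 ± 0.19 and CXCL5 by 3.07 ± 0.21 (SE), both of them neutrophil chemokine genes. Of 11 S100 genes, 7 rose and 4 did not pass, and adjusted over the list alone 7 rose and 1 fell. S100A12 rose by 2.91 ± 0.27 (SE) and S100A10 by 2.16 ± 0.17, and S100A11 stood at 3909 ± 1155 FPKM (SD, n = 2) in the controls and 2253 and 3168 FPKM in the co-cultures. The median of the S100 list was 1.21 higher with HepG2 and 1.42 higher with MHCC-97H, and 0.29 higher in control 2 than in control 1.

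Markers of tumour-associated and alternatively activated macrophages moved both ways. Of 15 tested, 5 rose, 5 fell and 5 did not pass, and adjusted over the list alone 6 rose and 5 fell. Besides IL10, the immune checkpoint ligand gene CD274 rose by 3.08 ± 0.16 and the angiogenic factor gene VEGFA by 1.61 ± 0.14 (SE). Besides MSR1, the lipid receptor gene TREM2 fell by 3.12 ± 0.17, SPP1, the osteopontin gene, fell by 1.99 ± 0.23, and the scavenger receptor gene CD163 fell by 1.77 ± 0.17 (SE). Of 19 genes of macrophage and monocyte identity, 3 rose, 9 fell and 7 did not pass, and adjusted over the list alone 3 rose and 11 fell. The lipopolysaccharide co-receptor gene CD14 rose by 3.28 ± 0.16 and the Fc receptor gene FCGR2A, whose reads can be shared with close copies, by 2.20 ± 0.16 (SE). Besides CD36, the integrin gene ITGAM fell by 2.40 ± 0.17, the lysosomal marker gene CD68 fell by 1.44 ± 0.15 and CSF1R, the receptor gene of a macrophage growth factor, fell by 1.19 ± 0.18 (SE).

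All 6 tested metallothionein genes, which encode metal-binding proteins, rose, also adjusted over the list alone. MT2A went from 32.9 ± 8.87 FPKM (SD, n = 2) to 973 and 1057 FPKM, and MT1F rose by 3.50 ± 0.15 on the log2 scale (SE). The list's median was 3.39 higher with HepG2 and 3.45 higher with MHCC-97H. MT1 genes resemble each other closely, so the split of reads among them is uncertain. Of 22 genes of hypoxia and glycolysis, 14 rose and 8 did not pass, and adjusted over the list alone 15 rose. BNIP3, a mitophagy gene induced by hypoxia, rose by 2.54 ± 0.13, ALDOC, an aldolase gene, by 2.52 ± 0.21, NDRG1 by 2.02 ± 0.15 and the glucose transporter gene SLC2A1 by 1.46 ± 0.15 (SE). GAPDH, another glycolytic gene, stood at 1449 ± 441 FPKM (SD, n = 2) in the controls and 1155 and 1541 FPKM in the co-cultures. Of 18 genes of endoplasmic reticulum stress and the amino acid response, 5 rose, 1 fell and 12 did not pass, and adjusted over the list alone 8 rose and 1 fell. DDIT4 rose by 1.63 ± 0.21 (SE) and SLC7A11, the cystine transporter gene, by 1.36 ± 0.26, and the transcription factor gene ATF3 fell by 2.39 ± 0.14. Of 11 heat shock genes, 2 rose and 9 did not pass, also adjusted over the list alone. The 2 were HSPA1A and HSPA1B, near-identical copies at 0.74 ± 0.17 and 0.66 ± 0.16 (SE), between which the split of reads is uncertain. With the pair as a block, 12 of the 18 stress genes rose and 1 fell (adjusted over the list alone 13 and 1), and 7 of the 11 heat shock genes rose and 3 fell, also adjusted over the list alone.

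Genes of lipid handling, lysosome and matrix fell more often than they rose. Of 15 LXR and PPARG target genes of lipid handling, 1 rose, 8 fell and 6 did not pass, with the same counts adjusted over the list alone. Besides FABP4 and APOC1, APOE, an apolipoprotein gene, fell by 3.28 ± 0.16, LPL, the lipoprotein lipase gene, fell by 2.61 ± 0.19, and NR1H3, the gene of the sterol receptor LXR alpha, fell by 2.48 ± 0.15 (SE). The member that rose was SREBF1, a regulator of fatty acid synthesis, at 0.57 ± 0.15 (SE). Of 18 lysosomal genes, 9 fell and 9 did not pass, and adjusted over the list alone 10 fell. LIPA, which encodes lysosomal acid lipase, fell by 2.45 ± 0.23 and NPC2, a cholesterol carrier gene, fell by 2.44 ± 0.28 (SE). Of 20 genes of matrix remodelling, 1 rose, 11 fell and 8 did not pass, with the same counts adjusted over the list alone. The metalloproteinase gene MMP19 fell by 2.83 ± 0.16, MMP9 fell by 2.08 ± 0.18, the collagen gene COL4A1 fell by 2.17 ± 0.25, and SERPINB2, a plasminogen activator inhibitor gene, rose by 1.11 ± 0.14 (SE).

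Of 11 NRF2 and iron genes, 1 rose, 4 fell and 6 did not pass, and adjusted over the list alone 2 rose and 5 fell. The haem oxygenase gene HMOX1 fell by 2.50 ± 0.14 and the hepcidin gene HAMP, an iron regulator, fell by 3.27 ± 0.22 (SE). Of 6 complement genes, 1 rose, 3 fell and 2 did not pass, with the same counts adjusted over the list alone. CFD, the factor D gene, fell by 2.28 ± 0.14 and the C5a receptor gene C5AR1 fell by 1.44 ± 0.14 (SE). Of 11 interferon-stimulated genes, none rose, 2 fell and 9 did not pass, and adjusted over the list alone 2 rose and 5 fell. The 2 were USP18 at -1.60 ± 0.18 and IFI6 at -1.41 ± 0.16 (SE). Of 14 cell cycle genes, 1 rose, 4 fell and 9 did not pass, with the same counts adjusted over the list alone. The mitotic activator gene CDC20 fell by 2.18 ± 0.16 and RRM2, a ribonucleotide reductase gene, fell by 1.03 ± 0.18 (SE). Of 20 cholesterol synthesis genes, 3 rose and 17 did not pass, and adjusted over the list alone 1 rose. Of 5 MHC class II genes, 1 fell and 4 did not pass, and adjusted over the list alone 1 rose and 1 fell. The faller over all genes was the invariant chain gene CD74 (-0.56 ± 0.14, SE). None of the 33 ribosomal protein genes passed, over all genes or adjusted over the list alone, with medians of -0.47 and -0.18 in the co-cultures. With the library pair as a block, 24 of the 33 ribosomal protein genes fell and 9 did not pass, and adjusted over the list alone 26 fell. In that fit 2 of the 11 interferon-stimulated genes rose and 7 fell, and adjusted over the list alone 3 rose and 8 fell. Of the 5 MHC class II genes 3 rose and 1 fell in that fit, also adjusted over the list alone. Of the 11 NRF2 and iron genes 2 rose and 7 fell in that fit, and adjusted over the list alone 3 rose and 7 fell.

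**Figure D2:**
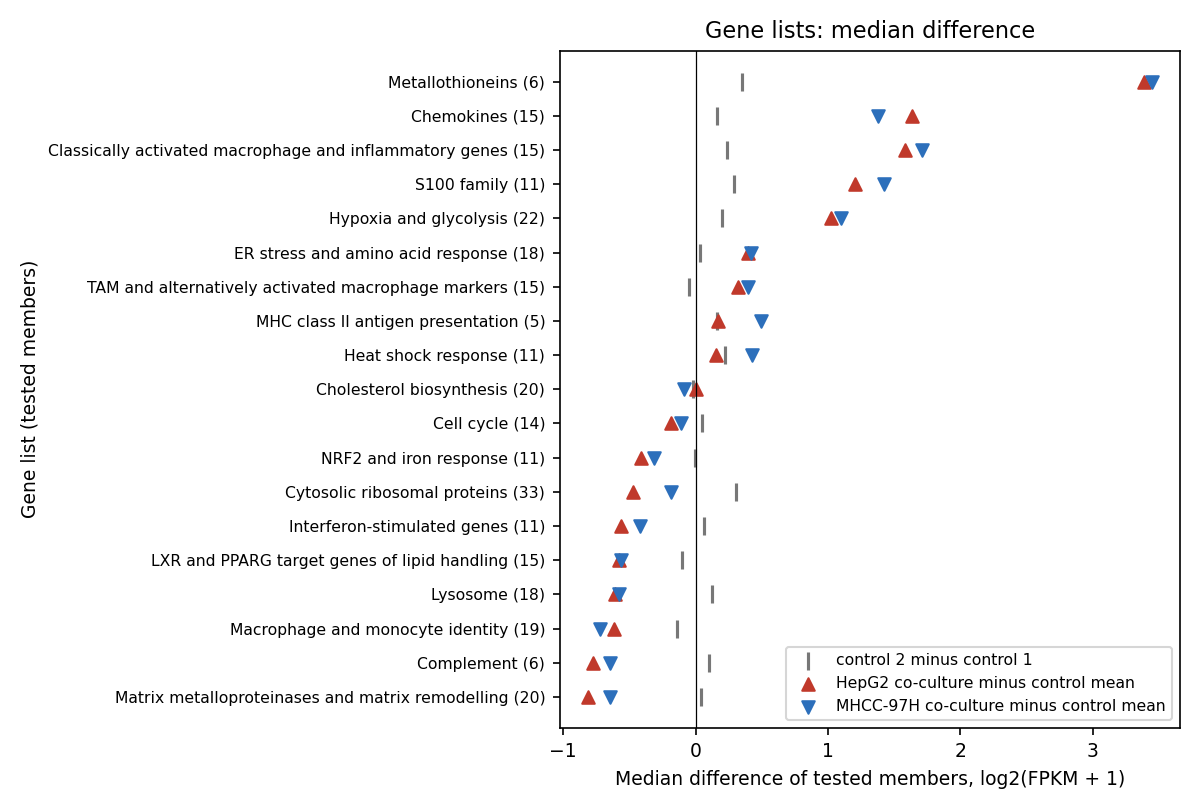
Median difference on log2(FPKM + 1) of the tested members of each gene list with at least 5 tested members, for each co-culture against the mean of the 2 controls and for control 2 against control 1. Metallothioneins, at 3.39 and 3.45, lie furthest right, and matrix remodelling genes, at -0.81 and -0.65, among those furthest left.

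Transcripts typical of the hepatoma cells were looked for next. ALB, the albumin gene, was at 0.0724 FPKM in both co-cultures and at 1.24 and 0.172 FPKM in the controls. The alpha-fetoprotein gene AFP and the epithelial genes KRT19 and EPCAM were listed at 0 in all 4 libraries. So were all 13 mitochondrially encoded genes, which every cell uses, so a listed 0 does not show a low level. The keratin genes KRT8 and KRT18 reached at most 0.568 FPKM in a co-culture. Of 24 hepatocyte genes, 2 were tested, of which 1 rose and 1 fell, also adjusted over the list alone. ORM1, an acute-phase protein gene, rose by 1.86 ± 0.21 to 3.63 and 5.21 FPKM, though its reads can be shared with a close copy, and the glypican gene GPC3 fell by 2.34 ± 0.25 (SE). Of 16 epithelial genes, 3 were tested and 1 rose, also adjusted over the list alone. This was the claudin gene CLDN7, at 0.88 ± 0.16 (SE), while KRT7 stood at 2.47 ± 1.14 FPKM (SD, n = 2) in the controls and 1.87 and 4.51 FPKM in the co-cultures.

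With HepG2 alone, S100A9 was 82.0-fold, IL6 251-fold, IL23A 138-fold and CCL1 122-fold above the mean of the controls in FPKM. MSR1 was at 0.0188 and FABP4 at 0.0157 of the control mean. By size, 931 genes (8.7%) were at least 2-fold from each control, 421 higher and 510 lower. In the limma fit of 3 groups, 1796 genes passed, 845 higher and 951 lower. Of the lists, 11 of 15 genes of classical activation rose and 1 fell, also adjusted over the list alone, and 13 of 22 hypoxia and glycolysis genes rose, 14 adjusted over the list alone. Of the lipid handling genes, 5 of 15 fell, 6 adjusted over the list alone. HepG2 co-culture has 1 library, so these p-values rest on the spread between the controls, and without a filter on low values 0 genes passed in limma (3004 at an unadjusted p under 0.05). Against control 1 alone 1173 genes were at least 2-fold apart by size and against control 2 alone 1517, where the 2 controls differed by as much on 155 genes (1.4%).

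With MHCC-97H alone, S100A9 was 76.2-fold, IL6 273-fold, IL23A 150-fold and CCL1 170-fold above the mean of the controls in FPKM. MSR1 was at 0.012 and FABP4 at 0.0198 of the control mean. By size, 897 genes (8.4%) were at least 2-fold from each control, 377 higher and 520 lower. In the limma fit of 3 groups, 1568 genes passed, 636 higher and 932 lower. Of the lists, 10 of 15 genes of classical activation rose, also adjusted over the list alone, where 1 fell as well, and 13 of 22 hypoxia and glycolysis genes rose, 16 adjusted over the list alone. Of the lipid handling genes, 6 of 15 fell, also adjusted over the list alone. MHCC-97H co-culture also has 1 library, and without a filter 0 genes passed in limma (2836 at an unadjusted p under 0.05). Against control 1 alone 1272 genes were at least 2-fold apart by size and against control 2 alone 1148.

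The co-cultures were then compared with each other, to see whether the lines moved the same genes. S100A9, S100A8, IL10, IL6, FABP4 and MSR1 moved in the same direction with both lines. In the library pairs that the authors' deposited tables set together (control 1 with HepG2, control 2 with MHCC-97H), S100A9 was 118-fold higher in the per-library FPKM of the first pair and 58.5-fold higher in the second. IL10 was 48.0-fold and 29.2-fold higher. By size, 757 genes were at least 2-fold from each control in both co-cultures, 328 higher and 429 lower, and 0 in opposite directions. These were 81.3% of the genes counted for HepG2 and 84.4% of those for MHCC-97H. Simulated unchanged groups with shared simulated controls had 2.38 genes in common on average and at most 6. The simulations gave genes of the same level the same spread and had no library pairs, so chance overlap may be larger. Independent lists would share 14.8 higher and 24.7 lower genes. Across genes, the log2 differences correlated with r = 0.902, against 0.334 in the simulations, and their covariance was 0.487 against a simulated 0.041. The simulated r is set by the design, since both differences use the same 2 controls. With 1 control for each co-culture, r was 0.890 for the pairs named above and 0.669 for the crossed pairs. No control is shared in that split, so shared controls cannot give these 2 correlations, each of which rests on 1 control per co-culture. Part of the overlap and of the covariance above may still come from the shared controls.

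Between the co-cultures themselves, 41 of 10735 genes passed in the limma fit of 3 groups, 12 higher and 29 lower with MHCC-97H (291 at an unadjusted p under 0.05). CEBPB, a transcription factor gene of inflammatory macrophages, was at 893 FPKM with HepG2 and 272 FPKM with MHCC-97H, a difference of -1.71. The controls differed about as much on this gene, by -1.75, at 615 FPKM in control 1 and 183 FPKM in control 2, and within the library pairs CEBPB was 1.45-fold and 1.49-fold higher in co-culture. PTGDS, a prostaglandin D synthase gene, was at 0.613 FPKM with HepG2 and 4.30 FPKM with MHCC-97H, a difference of 1.72, and at 12.6 and 11.1 FPKM in the controls. KDM6B, a histone demethylase gene, was at 43.2 FPKM with HepG2 and 17.4 FPKM with MHCC-97H, a difference of -1.26, and at 19.5 and 13.9 FPKM in the controls. These 3 genes were chosen after their values were seen. Each co-culture has 1 library, and the p-values rest on a spread shared over genes, so they compare these libraries and do not show a difference between the lines. Of the 41 genes, 31 differed in the same direction between control 2 and control 1, and 11 were under 0.01 FPKM in at least 1 library. The largest differences included readthrough genes, between which and their neighbours the split of reads is uncertain. Examples, also chosen after their values were seen, were RPL36A-HNRNPH2 at 5.57, FMC1-LUC7L2 at 3.36 and NDUFC2-KCTD14 at -3.45, where NDUFC2 itself was at 1.83. In limma with a mean of at least 5 FPKM 23 genes passed, and without a filter 0 (921 at an unadjusted p under 0.05).

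**Figure D3:**
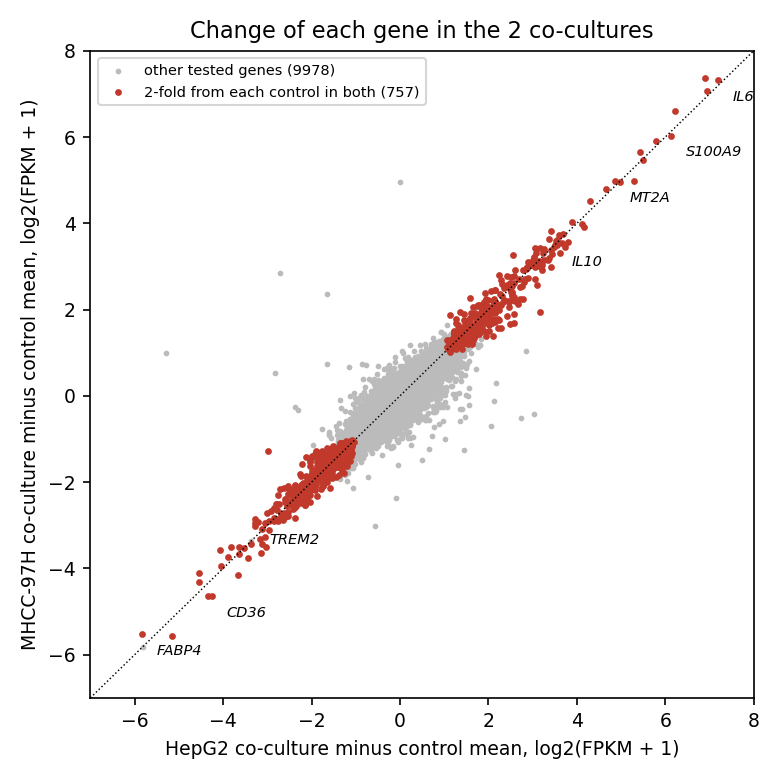
Difference from the mean of the 2 controls on log2(FPKM + 1), with HepG2 co-culture on the horizontal and MHCC-97H co-culture on the vertical axis and 1 point per tested gene. The 757 genes at least 2-fold from each control in both co-cultures, in red, lie along the dotted line of equal change.

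The authors' own comparisons list fewer genes. The authors' deposited table for HepG2 holds 124 genes, 62 higher and 62 lower in co-culture, and the authors' deposited table for MHCC-97H holds 114 genes, 57 higher and 57 lower. Both tables list 81 genes in common, 41 higher and 40 lower in each of the authors' deposited tables. The FPKM in the authors' deposited tables are those of the same libraries times a near-constant factor, so their directions are bound to match those found here. Of these genes, 104 for HepG2 and 97 for MHCC-97H were tested here, and all of them passed limma for either co-culture and lay at least 2-fold from each control. In all, 20 genes of the authors' deposited table for HepG2 and 17 of that for MHCC-97H were listed at 0 in 1 library.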

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

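The tests in this part were chosen after the result was seen, except the one on transcript length and GC content.

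The difference between the co-cultures was singled out because a test of it passed for 41 genes, CEBPB among them with a log2 difference of -1.71 for MHCC-97H minus HepG2. That test sets 1 library against 1 with a spread shared over genes, and the controls differed by -1.75 on CEBPB, so it does not show a difference between the lines.

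Across the 10735 tested genes, the difference MHCC-97H minus HepG2 correlated with control 2 minus control 1 at r = 0.558, although the 2 differences share no library. This is what a batch shared by control 1 with HepG2 and by control 2 with MHCC-97H would give. These are the pairs set together in the authors' deposited tables, and a shared batch remains a candidate explanation. The same pairs had the fullest windows of low-value ratios, at 13.2% and 7.3%, the cause of which was not tested. A trend with transcript length and GC content, which took up 13.9% and 12.8% of the variance of the 2 differences, lowered r from 0.612 to 0.556 over the 10554 genes with both values, so it is not the whole cause. Of the 41 genes, 31 differed in the same direction between the controls, but this count restates the correlation and decides nothing about the tumour lines. A difference between the lines cannot be told apart from the library pairs, as each line has 1 library. After the difference between the controls was subtracted, 19 of the 41 genes remained at least 2-fold apart, counting only genes at 0.01 FPKM or more in all libraries. The 41 were selected for a difference between the co-cultures, so some remainder follows from that choice. The slope on the control difference was 0.457 across the tested genes, so full subtraction can take off too much. The 19 therefore do not show a difference between the lines. Readthrough genes such as FMC1-LUC7L2 and ATP6V1G2-DDX39B are among these 19, and the split of their reads is uncertain.

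Both co-cultures moved the same genes, with a covariance of 0.487. Shared control libraries gave a covariance of 0.041 in simulations without library pairs, which leaves 0.446. With a different control for each co-culture, r was still 0.890 and 0.669, so shared controls are not the whole cause. RNA of the tumour cells in the macrophage libraries would bring their abundant keratin transcripts, yet KRT8 and KRT18 reached at most 0.568 FPKM in a co-culture. A response common to both lines was not tested and stays open. So does anything else that set the co-cultures apart from the controls, such as the membrane inserts, the medium or the time in culture.

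IL10 rose while MRC1 stayed near 0, although the study names both as markers of the co-cultured macrophages. MRC1 has a near-identical entry, both under retired identifiers, and a candidate explanation is that reads of near-identical genes were discarded. Of 6 other near-identical gene pairs, 5 had both members at a mean of at least 1 FPKM, with SMN1 at 17.7 and SMN2 at 18.0 FPKM, so a general loss of such reads is argued against. A low level of the transcript in THP-1 macrophages and a loss specific to this locus stay open. The current identifier is not among the genes listed, so no value under it could be examined.

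Of the 3 ways to split the 4 libraries into 2 and 2, 1 gave as many genes as the real split (2085), which was the real one, and the highest of the others gave 0. With 3 splits no share under 0.05 can be reached.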

How the results depend on the processing

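The fit with the library pair as a block was added after seeing the data. With control 1 paired with HepG2 and control 2 with MHCC-97H, as in the authors' deposited tables, limma called 4993 genes for either co-culture in place of 2085, and all 2085 were among them. Without a filter on low values, limma called 0 genes for HepG2, 0 for MHCC-97H and 0 between the co-cultures (3004, 2836 and 921 at an unadjusted p under 0.05), and 1522 for either co-culture. The cause was not tested. With a mean of at least 5 FPKM, 23 genes differed between the co-cultures, among 7677 tested in place of 10735. By size, a pseudocount of 5 gave 512 genes for HepG2 and 485 for MHCC-97H, and a fold limit of 3 gave 409 and 380, as each raises the change a gene needs. Leaving out 1 control gave 1173 to 1517 genes for HepG2, the highest without control 1. For either co-culture, leaving out 1 library gave 1565 to 2428 genes, where the lone library of a group is assumed to vary like the others. The other counts stayed within 1.5 times, and no named gene changed direction under any alternative run on it. Of the list medians under the alternatives, 113 moved by less than the spread between the controls and 55 by more, and the sign turned for heat shock genes with HepG2 (0.15, and -0.10 without control 1) and for cholesterol synthesis genes with HepG2 (0.00, and -0.10 without control 2). The test of 1 co-culture without 1 control has no residual degrees of freedom, and the alternatives on read counts were not run. The depth is unknown, so no counting error could be given for changes of genes near 0 FPKM.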

Other observations

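The tests on PPARG, on the zinc exporter and on glucocorticoid-induced genes were set before their values were seen, and the scan of gene symbols was chosen after the results were seen. The other genes named in this part were chosen after their values were seen.

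Genes with interleukin symbols rose more often than other genes. Of 36 tested genes whose symbols start with IL and a number, 17 (47.2%) rose in either co-culture, against 8.51% of all tested genes (two-sided Fisher's exact test, adjusted p = 3.80e-07 over 372 tests of symbol families and directions). IL24 went from 13.8 ± 0.34 FPKM (SD, n = 2) to 376 and 412 FPKM, IL11 from 7.25 ± 1.02 to 142 and 130 FPKM, and the decoy receptor gene IL1R2 from 5.10 ± 0.60 to 118 and 137 FPKM. CSF3, a granulocyte growth factor gene, went from 19.2 ± 2.20 to 297 and 329 FPKM. IL6R, the interleukin-6 receptor gene, fell by 1.21 ± 0.19 on the log2 scale (SE). Genes are not independent replicates, so the p describes these libraries.

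Among the families that fell more often than other genes were collagens (8 of 15, 53.3%), metalloproteinases (7 of 12, 58.3%), genes with CD symbols (18 of 50, 36.0%) and solute carriers (39 of 201, 19.4%), against 10.91% of all tested genes. Genes with CD symbols moved both ways, since 11 of the 50 (22.0%) rose, against 8.51% of all tested genes (two-sided Fisher's exact test, adjusted p = 0.073). COL22A1, a collagen gene, fell by 2.84 ± 0.23 and COL4A2 fell by 2.66 ± 0.23 (SE). The receptor gene CD22 fell by 2.85 ± 0.20 and CD84 fell by 2.51 ± 0.21 (SE). Of 300 tested zinc finger genes with ZNF symbols, 4 rose and 6 fell.

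A lower level of PPARG, the gene of a nuclear receptor that drives FABP4 and CD36, was set as a hypothesis for the fall of lipid handling genes. PPARG went from 21.5 ± 0.50 FPKM (SD, n = 2) to 6.14 FPKM with HepG2 and 4.64 FPKM with MHCC-97H, a log2 difference of -1.825 ± 0.176 (SE; limma adjusted p = 0.00134). This is consistent with the hypothesis, but the libraries show only that both fell together, and receptor activity was not measured.

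The rise of all 6 metallothionein genes was set against 2 hypotheses, zinc or another metal acting through the transcription factor MTF1 and a glucocorticoid-type response. The MTF1 target and zinc exporter gene SLC30A1 had a log2 difference of 0.262 ± 0.273 (SE; limma adjusted p = 0.547), where a rise of at least 1 in both co-cultures had been predicted. SLC30A1 differed by 0.466 with HepG2 and 0.058 with MHCC-97H, so the predicted rise was not seen. Both values lay within the limit of 0.5 set in advance. Within the library pairs it was 0.12 with HepG2 and 0.40 with MHCC-97H. With the pair as a block, a fit added after seeing the data, the SE was 0.124. The SE without pairs was larger than the difference itself, and this is 1 target gene, so the first hypothesis is not decided. The zinc importer genes SLC39A8 and SLC39A14 rose by 2.40 ± 0.30 and 1.10 ± 0.17 (SE). The 5 tested glucocorticoid-induced genes had a median of 0.056, at 0.083 with HepG2 and -0.067 with MHCC-97H. A median rise of at least 0.5 in both co-cultures had been predicted and was not seen. Both medians met the limit set in advance as the outcome against such a response. FKBP5 was higher by 1.37, and PER1 and DUSP1 were at -0.87 and -0.63. Members thus moved both ways, a condition not among the limits set in advance, so the median alone does not decide and the second hypothesis stays open.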
